A study of Bos taurus with 8 samples.

How the data were processed

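Expression was measured in 8 biopsies of lactating mammary gland from 4 Holstein cows, 1 full (12 h since milk removal) and 1 empty (0 h) per cow. Per the labels' protocols, total RNA was isolated with Trizol and purified on RNeasy columns, and 2 ug was reverse transcribed from an oligo(dT) primer and transcribed into biotinylated cRNA. The table holds 1 log2 value per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises probes, and its version is not given in the sources used here. The log2 scale was read from the deposited values, which lie between about 4.98 and 14.43 with nearly equal distributions in all 8 columns. Priming from the poly(A) tail makes 5' probe sets sensitive to RNA breakage, and quantile normalization forces equal distributions, so a shift shared by most genes cannot be seen.

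The table has 24128 probe sets, of which 112 platform controls were left out of the tests, and no missing values. Of the 24016 tested, 13292 had 1 gene symbol, 86 had several and 10638 had none in the annotation, and none was named from a probe set with several. That annotation can be old, so symbols were compared through entrez numbers with the RefSeq genes of ARS-UCD2.0: 13263 probe sets matched and 0 symbols changed. A gene was represented by its brightest probe set among those with 1 symbol, giving 9155 genes, 2913 of them with more than 1 probe set. No reference genome was used, so no coordinates are given.

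The main model was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the values as deposited, with state and cow as fixed terms, Benjamini-Hochberg adjustment over all 24016 probe sets and a threshold of 0.05. The fit had 3 residual and 2.81 prior degrees of freedom. Each standard error (SE) given for a log2 difference is limma's moderated one, which borrows from other probe sets. Cow was a block because the sample descriptions name a full and an empty sample for each cow. As a check, deviations from the group means correlated between libraries of the same cow at r = 0.457, 0.319, 0.598 and 0.525, and at -0.03 or below between cows. Differences between cows were tested with limma's F-test of the cow terms. Both samples of a cow come from 1 animal, so that test compares these 4 animals.

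Before the data were examined, 20 process lists and 10 cell type lists were fixed, and the rule for named genes with them. The lists cover milk proteins, milk fat, lactose, transport, junctions, STAT5 and STAT3 signalling, immediate early genes, involution, innate immunity, protein, heat and oxidative stress, hypoxia, serotonin, the clock, the cell cycle, ribosomes, the respiratory chain and cholesterol, and markers of the cell types a biopsy could hold. Lists were tested with camera (preset correlation 0.01, adjusted over 30 lists), and with an estimated correlation and fry as alternatives. The rule took up to 12 genes per direction among those passing with a direction shared by all cows. If none passed, it took the 6 with the smallest unadjusted p in that direction of the mean. It added all milk protein genes, up to 2 members of each list with the smallest unadjusted p where none passed, and the 6 genes that differed most clearly between cows. Placeholder symbols were passed over. Other list members, the platform controls (actin, 5' to 3' and the Bio and CreX controls) and further probe sets were named after their values were seen.

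The other alternatives were no replicate block, cow as a random block, median centring, repeated quantile normalization, only the brighter probe sets, each replicate left out, an intensity trend with robust prior, other thresholds, a 1.5-fold minimum and the mean of a gene's probe sets. After seeing the data, models without cows 2 and 4, with array weights and with the 5' minus 3' difference as a covariate were added. List medians were set against 10000 random lists matched on expression in 10 bins, using numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 for tables.

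The model was tested on simulated data with the 24016 probe sets, the spreads as moderated by limma and independent noise. It recovered 50.4% of probe sets changed by 1.5-fold, 93.7% by 2-fold and 100% by 4-fold, with 5.6% false calls. The simulated noise was alike in all cows, while the measured differences were wider in cows 2 and 4. Many probe sets were also changed together in each draw, which eases the Benjamini-Hochberg threshold compared with a lone change. These shares are therefore not the power reached in the real data. With 9155 independent genes, camera called 0 lists when none was shifted, and called a list shifted by 0.3 log2 in 100% of 20 draws. In the real data, the lists that passed camera had estimated correlations between genes of 0.09 to 0.91. The draws with independent genes therefore do not measure how often camera calls a list falsely in the real data.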

Results

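Gene expression was measured in biopsies of lactating mammary gland from 4 Holstein cows (Bos taurus). Each cow gave 1 sample at 12 h since milk removal, when the labels call the gland full, and 1 sample at 0 h, when they call it empty. The 8 RNA samples were hybridised to 8 single-colour arrays of bovine probe sets, each a group of short probes for 1 transcript. The series asks how milk accumulation affects expression in the gland, and full was compared with empty gland within each cow. Anything else that differed between the samplings cannot be told apart from the state. The order of the biopsies and the gland of the udder that each came from are not given in the sources used here.

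Array signals have no read depth, and the number of arrays limits the precision. The median log2 level of an array lay between 7.08 and 7.24, and the values spanned about 4.98 to 14.43. Across the 24016 probe sets, which are not independent replicates, full and empty libraries of the same cow correlated at r = 0.995 in cow 1, 0.977 in cow 2, 0.995 in cow 3 and 0.985 in cow 4. The full libraries of cows 2 and 4 stood apart from the rest, with median correlations to the other 7 arrays of 0.969 and 0.9753, against 0.9856 or above for the remaining 6 libraries. The SD of the full minus empty differences was 0.19 in cow 1, 0.38 in cow 2, 0.17 in cow 3 and 0.30 in cow 4. More than 2-fold higher levels in full gland were seen for 5, 311, 4 and 264 probe sets in cows 1 to 4, and more than 2-fold lower levels for 22, 250, 5 and 13.

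The 6 genes named as higher in the full gland, those with the smallest unadjusted p among genes with a higher mean, differed by 1.26-fold to 2.35-fold. Each of them was higher in all 4 cows, which picking by the smallest p favours. CCN1, a secreted matricellular protein of the immediate early class, was higher by 1.24 ± 0.25 log2 (limma's moderated SE, n = 4 cows, as for each SE below), from 8.72 ± 0.34 in empty to 9.95 ± 0.78 in full gland (SD, n = 4). Its relative CCN2 was higher by 0.64 ± 0.12 and ADAMTS1, a secreted metalloproteinase, by 0.81 ± 0.11. F3, the tissue factor that starts blood clotting, was higher by 0.77 ± 0.19, CFL2, an actin-severing cofilin, by 0.34 ± 0.08 and SIX3, a homeobox transcription factor, by 0.34 ± 0.08. The SIX3 signal was dim, at 6.11 in empty and 6.45 in full gland, below the median level of the arrays. The second probe set of ADAMTS1 was higher by 0.42 and went the same way in 3 of the 4 cows. No gene passed the limma test over all probe sets, and each of these 6 had an adjusted p of 0.993.

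The 6 genes named as lower were those with the smallest unadjusted p among genes with a lower mean. Each was lower in all 4 cows, which this choice favours. CCDC184 differed by -0.70 ± 0.17 log2 (SE, n = 4 cows), CDH16, a cadherin of kidney and other epithelia, by -0.69 ± 0.13 and MFSD2A, a transporter of lysophosphatidylcholine, by -0.59 ± 0.12. SLC39A12, a zinc transporter, differed by -0.43 ± 0.07, and STXBP6, a syntaxin-binding protein, by -0.31 ± 0.08. NEB, the muscle protein nebulin, differed by -0.64 ± 0.16, but 1 of its 3 probe sets went this way and the others differed by 0.03 and 0.13. CDH16 had 2 probe sets, and both were lower in all 4 cows. The adjusted p was 0.993 for each of these 6 genes, so none passed.

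**Figure D1:**
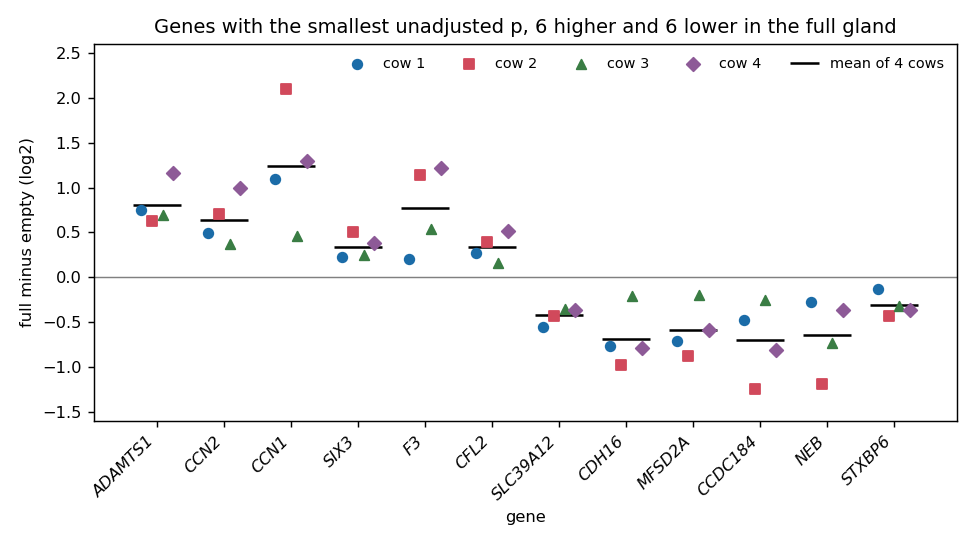
The log2 difference of full minus empty gland is plotted for 12 genes, 6 higher and 6 lower, with 1 point per cow and a bar at the mean of the 4 cows. Genes were picked by the smallest unadjusted p in each direction. For each of them all 4 points lay on the same side of 0, which this choice favours. The widest range was that of CCN1 (0.46 to 2.09), and none of the genes passed the test.

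Over the whole array, 0 of 24016 probe sets and 0 of 9155 genes passed an adjusted p of 0.05 in limma with cow as a block, and the smallest adjusted p was 0.993. At an unadjusted p under 0.05 there were 600 probe sets, 263 higher and 337 lower, where 1201 would be called with no effect, and 256 genes. The 4 cows shared a direction for 10.2% of the probe sets (1013 higher, 1434 lower), where chance gives 12.5%. A mean change of 1.5-fold or more together with a shared direction was seen for 25 probe sets that were higher and 5 that were lower. A probe set of median spread would have needed a log2 difference of about 1.72 to pass as the only call.

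Milk protein transcripts lay near the top of the measured range in both states, and the brightest probe set of each differed by less than 0.05 log2. LALBA, the lactose synthase modifier alpha-lactalbumin, was at 14.20 ± 0.03 in full and 14.20 ± 0.05 in empty gland (SD, n = 4), and PAEP, beta-lactoglobulin, at 14.39 ± 0.03 and 14.38 ± 0.05. The caseins CSN1S1, CSN1S2, CSN2 and CSN3 differed by -0.03, -0.01, -0.01 and -0.04, with 95% intervals that together spanned -0.21 to 0.16. The other 2 probe sets of CSN2 differed by 0.02 and 0.11. The sign turned under median centring for PAEP, under repeated quantile normalization for CSN2 and with cow 2 left out for CSN1S1, CSN1S2, CSN2 and LALBA. The milk protein list had a median of -0.01 over 6 genes, none of which passed, and an adjusted p of 0.815 in camera, limma's test of a gene list against all other genes.

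Of the 30 gene lists set beforehand, 10 passed camera with its preset correlation of 0.01, with 5 higher and 5 lower in full gland. None of the 10 calls held when the correlation between genes was estimated, where the smallest adjusted p was 0.736, or with fry, which tests whether a list's genes move one way on balance and gave a smallest adjusted p of 0.704. No member of any list passed over all probe sets, and adjusted over the list alone 2 members passed, both in the immediate early list. The split of calls was 8 higher and 5 lower after repeated quantile normalization.

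The immediate early and mechanical stress list was the furthest above the other genes in full gland, with a median of 0.26 log2 over 26 genes (camera adjusted p = 2.8e-08, adjusted p = 0.736 with an estimated correlation). Of its members 21 were higher and 5 lower, and the 2 that passed adjusted over the list alone in limma were CCN1 and CCN2, with a smallest adjusted p of 0.0373. The transcription factors EGR1, ATF3 and JUN were higher by 0.84, 0.73 and 0.57, of which EGR1 was higher in all 4 cows. A second, dimmer probe set of EGR1, at 6.08 to 6.31, differed by -0.005 and was higher in 2 of the 4 cows. FOS was higher by 2.05 in cow 2 and 0.66 in cow 4 but differed by -0.33 in cow 1 and -0.17 in cow 3. The list's medians in cows 1 to 4 were 0.07, 0.66, -0.01 and 0.58, so that the shift lay mainly in the 2 full libraries that stood apart. Without cows 2 and 4 the median was 0.02 and the call was lost (camera adjusted p = 0.174).

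Tight junction and adherens junction genes were higher, with a median of 0.11 over 16 genes of which 15 were higher (camera adjusted p = 6.3e-04, adjusted p = 0.736 with an estimated correlation). Adjusted over the list alone none passed, and the smallest adjusted p was 0.155. The epithelial claudin CLDN4 was higher by 0.68 ± 0.18 (SE, n = 4 cows) and CLDN10 by 0.47 ± 0.16, both in all 4 cows. The medians in cows 1 to 4 were 0.02, 0.23, -0.02 and 0.20. Without cows 2 and 4 the median was 0.0018, although the camera adjusted p stayed at 0.0425.

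Cell cycle genes had a median of 0.08 over 25 genes, 18 of them higher (camera adjusted p = 0.027, adjusted p = 0.736 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A was higher by 0.28 on average and in all 4 cows, and MCM3, a part of the replicative helicase, by 0.26. CDKN1A restrains the cell cycle, so the member with the smallest p acts against the list's name. The medians in cows 1 to 4 were -0.17, 0.17, -0.01 and 0.41, and without cow 4 the median was 0.01 (camera adjusted p = 0.954), without cow 2 it was 0.06 (camera adjusted p = 0.0904) and without both -0.09.

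Milk fat genes were lower in full gland, with a median of -0.14 over 28 genes of which 26 were lower, 10 of them in all 4 cows (camera adjusted p = 8.8e-06, adjusted p = 0.736 with an estimated correlation). INSIG1, which retains the sterol-sensing SREBP complex in the endoplasmic reticulum, differed by -0.36 ± 0.10 (SE, n = 4 cows) and LPIN1, a phosphatidate phosphatase, by -0.42 ± 0.15. The fatty acid enzymes ACACA and FASN differed by -0.45 and -0.24, and SCD by -0.01. The medians in cows 1 to 4 were -0.01, -0.20, -0.01 and -0.26, and without cows 2 and 4 the call was lost at a median of -0.03 (camera adjusted p = 0.896).

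Cholesterol synthesis genes were lower as well, with a median of -0.17 over 15 genes of which 14 were lower, 4 of them in all 4 cows (camera adjusted p = 1.42e-05, adjusted p = 0.736 with an estimated correlation). The list's median was negative in every cow, at -0.06, -0.15, -0.11 and -0.38. MVD, a decarboxylase of the mevalonate pathway, differed by -0.30 ± 0.08 (SE, n = 4 cows) and NSDHL by -0.23 ± 0.08, while ACAT2 differed by 0.31. Without cows 2 and 4 the median was -0.04 and the call was lost (camera adjusted p = 0.73).

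Nuclear-encoded respiratory chain genes had a median of -0.09 over 31 genes, 29 of them lower (camera adjusted p = 9.14e-06, adjusted p = 0.736 with an estimated correlation), and the members with the smallest unadjusted p were CYC1 at -0.30 and SDHB at -0.17. Their medians in cows 1 to 4 were -0.02, -0.26, 0.01 and -0.16, and without cows 2 and 4 the median was -0.0045 (camera adjusted p = 0.347). Lactose synthesis and glucose uptake genes had a median of -0.13 over 11 genes, 9 of them lower (camera adjusted p = 0.014, adjusted p = 0.736 with an estimated correlation), with SLC35B1 at -0.23 and PGD at -0.17. That call was lost without cow 2 (camera adjusted p = 0.328) and without cow 4 (camera adjusted p = 0.0699). It was also lost with cow left out of the model (camera adjusted p = 0.0504).

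Genes of the unfolded protein and integrated stress response had a median of -0.10 over 22 genes, 16 of them lower (camera adjusted p = 0.0284, adjusted p = 0.736 with an estimated correlation). CHAC1, a glutathione-degrading target of ATF4, differed by -0.57 ± 0.14 (SE, n = 4 cows) and TRIB3, a pseudokinase induced by the same factor, by -0.39 ± 0.13. CHAC1 was lower in all 4 cows and by more in cow 1 (-0.89) and cow 3 (-0.86) than in cow 2 (-0.20) and cow 4 (-0.31). The list's call was lost without cow 1 (camera adjusted p = 0.185), without cow 2 (camera adjusted p = 0.118) and with cow left out of the model (camera adjusted p = 0.0614).

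The other process lists did not pass. Amino acid and ion transport genes had a median of -0.09 (10 of 16 lower, camera adjusted p = 0.156), with the amino acid carrier SLC7A5 at -0.32 and the aquaglyceroporin AQP3 at -0.44. Genes of prolactin and growth hormone signalling through STAT5 had a median of -0.09 (8 of 12 lower, camera adjusted p = 0.243), with the STAT5 target CISH at -0.32 and IGF1 at 0.17. Both of these lists passed as lower without cow 1 (camera adjusted p = 0.0241 for each), and the STAT5 list also among the brighter probe sets (camera adjusted p = 0.0362). Over the 4 cows each had an adjusted p = 0.736 with an estimated correlation. Genes of LIF, oncostatin M and STAT3 signalling had a median of 0.02 (8 of 13 higher, camera adjusted p = 0.625), with CEBPD at 0.22 and PIM1 at -0.30. Involution and apoptosis genes had a median of 0.07 (20 of 28 higher, camera adjusted p = 0.243), with IGFBP3 at 0.19 and the protease CTSD at -0.16. Chemokine, acute phase and innate immunity genes had a median of 0.05 (20 of 33 higher, camera adjusted p = 0.177), with PTX3 at 0.20 and MYD88 at -0.24.

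Oxidative stress defence genes had a median of 0.06 (15 of 20 higher, camera adjusted p = 0.0835), with PRDX6 at 0.16 and GPX3 at 0.31, and the list passed after repeated quantile normalization (camera adjusted p = 0.0395), among the brighter probe sets (0.034) and without cow 1 (0.0222), all with the preset correlation. Over the 4 cows it had an adjusted p = 0.736 with an estimated correlation. Circadian clock genes had a median of -0.05 (4 of 8 lower, camera adjusted p = 0.284), with RORA at -0.52 and HLF at -0.29, and passed as lower without cow 2 (median -0.24, camera adjusted p = 0.0124, but over the 4 cows adjusted p = 0.736 with an estimated correlation). Hypoxia and vascular genes had a median of -0.07 (13 of 21 lower, camera adjusted p = 0.625), with VEGFA at -0.18 and EDN1 at 0.44. Ribosomal protein genes had a median of -0.01 over 30 genes (camera adjusted p = 0.729), with RPS19 at 0.11 and RPL13 at -0.07. The ribosomal and circadian lists passed camera without cows 2 and 4, with the preset correlation. Over the 4 cows the ribosomal list had a camera adjusted p = 0.892 with an estimated correlation. For heat shock genes (median -0.01 over 15, camera adjusted p = 0.537) the sign of camera was the opposite one, with HSPB8 at 0.52 and CRYAB at 0.36. The same held for serotonin and PTHLH genes (median -0.0048 over 9, camera adjusted p = 0.877), with PTHLH at -0.23 and DDC at 0.46.

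**Figure D2:**
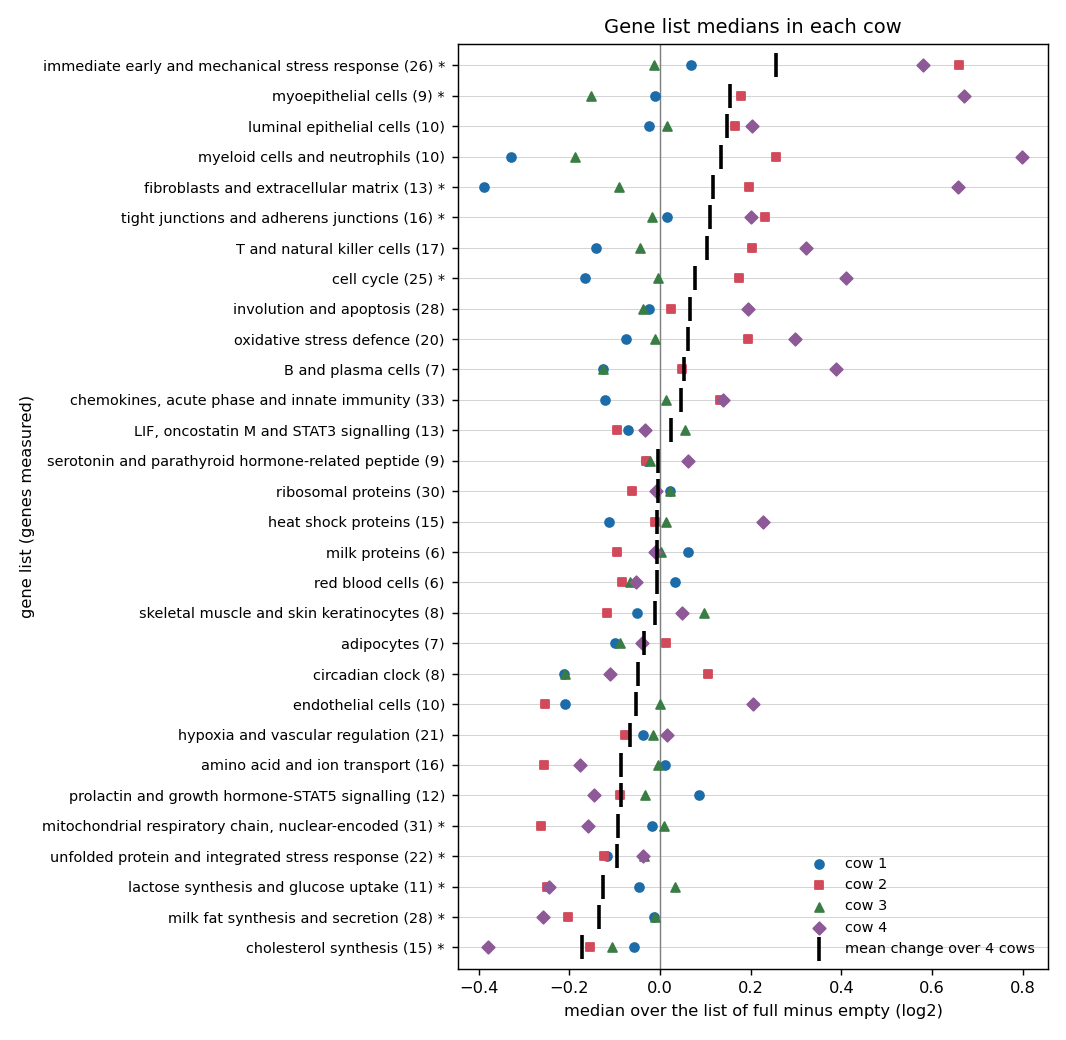
Each line is a gene list with the number of genes measured, and its points are the list's median log2 difference of full minus empty gland in cows 1 to 4. The bar is the median of the mean change over the 4 cows, and an asterisk marks the 10 lists that passed camera with the preset correlation, none of which passed with an estimated one. The points of cows 2 and 4 lay furthest from 0 in most of these lists, as in the immediate early list (0.66 and 0.58, against 0.07 and -0.01).

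Markers of non-luminal cells moved with the full library of cow 4. Fibroblast and matrix genes had a median of 0.12 over 13 genes (camera adjusted p = 0.0436, adjusted p = 0.736 with an estimated correlation), but 0.66 in cow 4 against -0.39, 0.20 and -0.09 in cows 1 to 3. Without cow 4 their median was -0.07, without cow 2 the call was lost (camera adjusted p = 0.126), and without both cows the list passed as lower (median -0.21, camera adjusted p = 0.0029). COL1A1 was higher by 1.06 and COL3A1 by 0.48 in cow 4, while they differed by -0.56 and -0.28 in cow 1. Myoepithelial genes had a median of 0.15 over 9 genes, all higher (camera adjusted p = 0.0195, adjusted p = 0.736 with an estimated correlation), and 0.67 in cow 4, with KRT17 at 0.20 and CNN1 at 0.30. Without cow 4 that median was 0.03 (camera adjusted p = 0.597). With cow left out of the model the fibroblast and myoepithelial calls were lost (camera adjusted p = 0.0826 and 0.0614).

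Myeloid and neutrophil genes had a median of 0.13 over 10 genes (camera adjusted p = 0.0734), which was 0.80 in cow 4 and -0.33 in cow 1, with MPEG1 at 0.32 and ITGB2 at 0.19. T and natural killer cell genes had a median of 0.10 over 17 genes (camera adjusted p = 0.0505), with CD8A at 0.31 and ZAP70 at -0.30. Both lists passed as higher without cow 1, where the camera adjusted p was 0.0084 for myeloid and 0.0099 for T and natural killer genes, and after median centring (0.0306 for each). Neither passed without cow 4. Their medians were negative in cows 1 and 3, at -0.33 and -0.19 for myeloid and -0.14 and -0.04 for T and natural killer genes. Without cows 2 and 4 the myeloid list passed as lower (median -0.24, camera adjusted p = 0.0038). These calls use the preset correlation, and over the 4 cows each list had an adjusted p = 0.736 with an estimated correlation. B and plasma cell genes had a median of 0.05 over 7 genes (camera adjusted p = 0.243), with MS4A1 at 0.19 and POU2AF1 at 0.17. Their median was 0.39 in cow 4 but -0.13 in both cow 1 and cow 3. Endothelial genes had a median of -0.05 over 10 genes (camera adjusted p = 0.395), with TEK at -0.22 and ENG at -0.20, and passed as lower without cow 4 (median -0.14, camera adjusted p = 0.0079, but over the 4 cows adjusted p = 0.798 with an estimated correlation).

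Luminal epithelial genes had a median of 0.15 over 10 genes (camera adjusted p = 0.156), with KRT18 at 0.61 and EHF at -0.18, and the list passed as higher among the brighter probe sets (median 0.20, camera adjusted p = 0.0351, but over all probe sets adjusted p = 0.736 with an estimated correlation). KRT18 was 1.36 higher in cow 4 and differed by -0.04 in cow 1. Adipocyte genes had a median of -0.04 over 7 genes (camera adjusted p = 0.537), with CFD at -0.16 and LEP at -0.14. Red blood cell genes had a median of -0.01 over 6 genes (camera adjusted p = 0.643), with AHSP at -0.11 and GYPC at -0.10. Genes of skeletal muscle and skin had a median of -0.01 over 8 genes while camera's direction was up (camera adjusted p = 0.877), with KRT10 at -0.28 and CKM at 0.18.

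RNA quality signs moved with the full library of cow 2. The mean difference between the 5' and 3' probe sets of 5 control transcripts was -1.91 log2 in that library, against -0.76, -0.85 and -0.83 in the full libraries of cows 1, 3 and 4 and -0.87, -0.92, -1.22 and -0.97 in the empty libraries of cows 1 to 4. With this difference as a covariate beside the cow block, 0 probe sets passed in limma and 1003 had an unadjusted p under 0.05. Without cows 2 and 4, 0 probe sets and 0 genes passed in limma, with 2150 and 879 at an unadjusted p under 0.05.

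**Figure D3:**
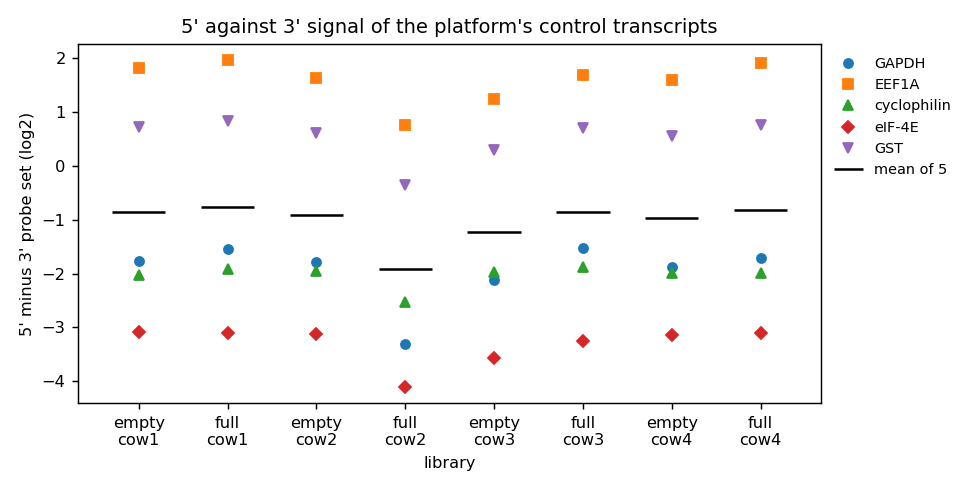
The log2 difference of the 5' minus the 3' probe set is plotted for 5 control transcripts in each of the 8 libraries, with a bar at their mean. The mean was -1.91 in the full library of cow 2 and between -1.22 and -0.76 in the other 7 libraries.

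Differences between cows passed the test for some genes. The clearest named differences were in the major histocompatibility complex (MHC), whose genes present peptides to T cells. The class I gene BOLA was at 5.91 in cow 1, the mean of its full and empty library, and at 13.02, 12.32 and 12.98 in cows 2 to 4 (limma adjusted p = 0.0011). BOLA-DQA2, a class II gene, was at 5.52 in cow 4 and at 10.25, 11.61 and 10.67 in cows 1 to 3 (limma adjusted p = 0.0013), and BOLA-N ranged from 5.60 in cow 1 to 8.84 in cow 4 (limma adjusted p = 0.0039). Full and empty libraries of the same cow differed by at most 0.58 for these 3 genes.

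Outside the MHC, AKR1C4, an aldo-keto reductase, was at 10.43 and 10.17 in cows 1 and 2 and at 7.25 and 7.12 in cows 3 and 4 (limma adjusted p = 0.0017). GSTO1, a glutathione transferase, was at 5.14 in cow 3 and at 7.37, 8.45 and 8.54 in cows 1, 2 and 4 (limma adjusted p = 0.0017). PRSS2, a trypsinogen, was at 5.80 and 5.74 in cows 1 and 4 and at 8.61 and 8.16 in cows 2 and 3 (limma adjusted p = 0.0039). In all, 105 probe sets differed between cows in limma's F-test with the state in the model, among them probe sets of 51 genes. Of the 26 probe sets annotated to BOLA genes, 14 were among the 105. The probe signal depends on both transcript amount and sequence match, and the arrays do not separate these. The count was 29, 131, 27 and 13 with cows 1 to 4 left out in turn.

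**Figure D4:**
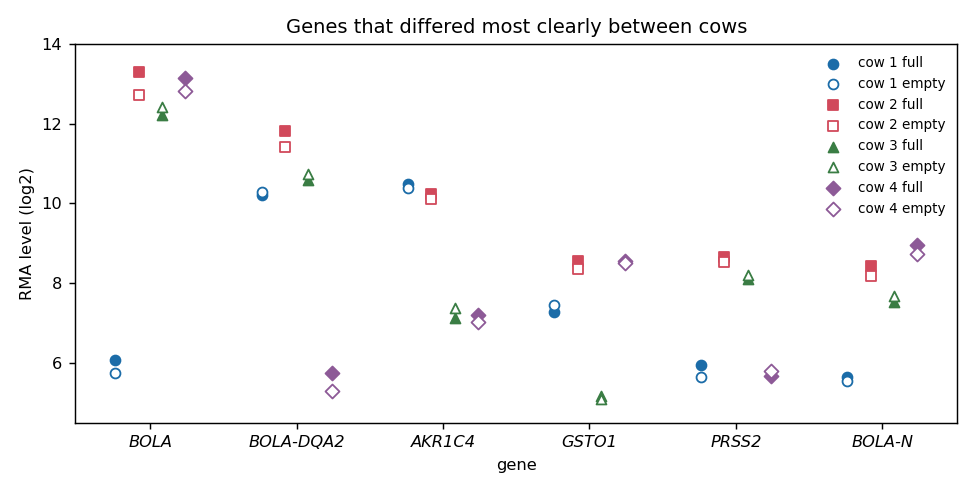
Log2 levels of 6 genes are plotted for the full (filled) and empty (open) library of each cow. The 2 libraries of a cow lay within 0.58 of each other for every gene shown, while cow means spanned 2.87 (PRSS2) to 7.11 (BOLA).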

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

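The tests on the cow 2 and cow 4 libraries, the left-out-cow test and the fibroblast comparisons were chosen only after the result was seen. The counts over other splits were written before. The YAP/TAZ target test concerns the 12 genes named from these data, so its question came after they were named. Its prediction was written before the targets used were examined, and 5 of the 26 listed were left out as already seen. Of 104 groups of 4 libraries, 12 held a library far from the other 3, where chance gives about 5.2 if the tests are independent. They reuse the same full and empty libraries with correlated measures, so the excess decides nothing.

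The first pattern is the full library of cow 2, whose mean 5' minus 3' difference was -1.909 against -0.851 to -0.756 in the other full libraries. Loss of 5' transcript ends in 1 RNA preparation may account for part of the distance, but the tables do not settle it: the difference was lower than in each of the other 7 libraries for 5 of 5 control transcripts, which is the observation itself. The full minus empty differences of cow 2 correlated at -0.247 and -0.344 across probe sets with those of cows 1 and 3, but at 0.396 with those of cow 4, although the 5' minus 3' difference was higher in full gland in all 3 of these cows. A larger share of other cell types cannot be told apart from it: 1 of 7 lists of stromal, myoepithelial and immune cells lay above the 95th percentile of matched random lists (fibroblasts, 98.6), and the myoepithelial, myeloid and T cell lists lay just under it at 93.4, 93.7 and 94.0, but the endothelial list lay at 2.5. A response of this cow to milk accumulation stays open and was not tested.

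The next pattern is the full library of cow 4, where the actin control read 7.93 with its 3' probe set (5.91 to 6.19 in the other full libraries) and 7.15 with its middle one (5.68 to 5.92). Loss of 5' transcript ends is argued against, because 5 of 5 control transcripts lay within the range of the other 7 libraries. The actin control was not among these 5, since its probe sets read 5.66 to 6.19 in the other 7 libraries, and in this one its 5' probe set was higher too, at 6.57. A larger share of other cell types may account for it: 6 of 7 stromal, myoepithelial and immune lists were above the 95th percentile, with COL1A1 higher by 1.06, but not the adipocyte list (24.1) nor, outside the 7, red blood cells (19.5) and skeletal muscle and skin (64.7). Members of the skeletal muscle and skin list went both ways, so its median does not decide on muscle. ACTA1, a skeletal muscle actin, read 7.81 in this library and 5.89 to 6.03 in the other 7, while KRT10 differed by -0.68 in cow 4. The luminal list was higher (97.9) but its members went both ways, with KRT18 at 1.36 and MUC1 at -0.46. A lower share of epithelium therefore stays open, and a response of this cow to milk accumulation stays open and was not tested. The platform controls BioB, BioC and BioDn, but not CreX, read lower in the full libraries of cows 2 and 4 than in all others. BioB read 9.63 and 9.50 there, against 9.78 or above, and BioC 10.90 and 10.91, against 11.15 or above. A difference in array processing that these 2 libraries share stays open and was not tested.

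The last pattern is the set of 12 genes picked by the smallest unadjusted p, none of which passed the test. All of them shared a direction in the 4 cows, which this choice favours. Genes picked by the same rule from 3 cows lay above the 95th percentile of matched random lists in the left-out cow for 2 of 4 cows (cows 3 and 4, both at 99.99, but 66.2 in cow 1 and 77.6 in cow 2), so selection of extreme values from noise cannot be told apart from a shared response. More fibroblasts are argued against for cows 1 and 3, where that list was at most -0.0911, while other cell types stay open (the skeletal muscle and skin list lay at 95.8 in cow 3). For cows 2 and 4 more fibroblasts cannot be told apart, since the list was higher by 0.1971 and 0.6585 there (11 and 13 of 13 members), below the 0.67 and 1.08 of the 6 genes. A YAP/TAZ transcriptional response is a candidate explanation: 9 unseen targets of 26 listed had a median of 0.17, at the 99.76 percentile of matched random lists, but -0.15 in cow 1. Of them 2 (ANKRD1, GADD45A) belong to the immediate early list whose median had been seen. The percentile is not distinctive, since lists that did not pass camera reached 99.99 (luminal) and 99.73 (involution). The targets CCDC80 (-0.51, 0.56, -0.33 and 0.97 in cows 1 to 4) and MYOF had the signs of the fibroblast list in each cow. CRIM1 was higher in all 4 cows.

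Other splits of the 8 libraries were compared with the real one, and a model with the cow block could be fitted for 32 of 35. For gene lists, 14 of the 32, the real one included, gave at least the real 10, and the highest other count was 15, so chance is not excluded. Of the 32, 24 part 2 pairs only and use 2 cows, and they are 12 fits each counted 2 times, because the block absorbs a cow that is not parted. That leaves 20 distinct fits, 9 of them with at least 10 lists. For probe sets and genes the real counts are 0, so that all 32 splits reach them whatever the data and the comparison decides nothing. The highest counts in any other split were 740 and 390, but that split keeps the real contrast in 2 of the cows. The 2 splits with 740 are the same fit and part only cows 2 and 4, with their full libraries on the same side. That fit is full against empty gland in these 2 cows, with the other cows left to measure the spread. The distance of these 2 full libraries from the rest and a response of these cows cannot be told apart. Any split that parts 2 pairs with both full libraries on the same side keeps the real contrast in those cows, so it is no measure of chance. The splits that part all 4 pairs number 8, too few for a share under 0.05. Among them the real split gave 10 lists and 600 probe sets at an unadjusted p under 0.05, and the highest other counts were 13 and 3474.

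Other libraries far from their group were as follows. CCN1 was at 9.22 in the empty library of cow 4, against 8.51 to 8.57, and MFSD2A at 8.92 there, against 9.45 to 9.54. CFL2 was at 8.52 in the full library of cow 4, against 7.98 to 8.07, and the milk fat list had a mean of 10.52 there, against 10.88 to 10.95. NEB was at 8.75 in the full library of cow 3, against 6.96 to 7.23. The mean of the oxidative stress list was 8.94 in the empty library of cow 3, against 9.23 to 9.29, and that of the fibroblast list 10.14 there, against 10.59 to 10.62. In the empty library of cow 1 the endothelial list was at 9.21, against 8.92 to 8.96, and the T and natural killer list at 7.35, against 7.02 to 7.05.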

How the results depend on the processing

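The settings without cows 2 and 4, with array weights and with the 5' minus 3' covariate were chosen only after the result was seen. The counts of probe sets and genes changed were 0 in limma under every setting run, with 220 to 2150 probe sets and 84 to 879 genes at an unadjusted p under 0.05.

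The 10 gene lists became 6 with no replicate block, 0 with an estimated correlation, 0 with fry, 5 without cows 2 and 4 (2 of them among the 10, of which the fibroblast list passed in the opposite direction) and 5 with array weights, and ranged from 7 to 14 with each replicate left out. Over all settings, a list lost its call 41 times, gained one 20 times and kept its pass or fail 316 times. In 8 more cases camera's direction turned for a list that passed in the main fit or in the setting. A list that passed in neither counts as kept even where its direction turned. The cow block changed no other call between full and empty. The 105 probe sets differing between cows became 208 after median centring, 248 with an intensity trend and robust prior, 30 at an adjusted p under 0.01, 255 under 0.10 and 1820 without cows 2 and 4, and ranged from 13 to 131 with each replicate left out. The cause was not tested.

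Some signs turned. PAEP was -0.0065 after centring and 0 after repeated quantile normalization, CSN2 0.0012 after the latter and 0.0403 as the mean of its probe sets. With each replicate left out, the ranges that crossed 0 included -0.0652 to 0.0049 for CSN1S1, -0.0057 to 0.0353 for PAEP, -0.0309 to 0.0184 for CSN1S2, -0.0307 to 0.0241 for CSN2, -0.0157 to 0.0108 for LALBA, -0.1658 to 0.0049 for GYPC, -0.011 to 0.5443 for MPEG1, -0.0525 to 0.2698 for POU2AF1, -0.0964 to 0.3845 for MS4A1 and -0.0663 to 0.2267 for the fibroblast list. Not every list whose median turned is given. The casein, LALBA and GYPC values turned without replicate 2, PAEP without replicate 1 and the rest of those given without replicate 4. Without cows 2 and 4 the medians were -0.0856 for cell cycle, -0.0937 for myoepithelial, -0.2122 for fibroblast and -0.2423 for myeloid genes, 0.0234 for ribosomal genes, and camera's direction turned for lactose (-0.0183) and respiratory chain genes (-0.0045). The cause was not tested. Milk protein signals lie near the top of the range, which limits what could be seen there.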

Other observations

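The genes, probe sets and pairs of cows in this part were chosen only after the result was seen.

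THBS1, which encodes the matricellular protein thrombospondin 1, had 6 probe sets, and 4 of them were higher in full gland in all 4 cows, by 0.59, 0.82, 0.82 and 1.06 log2. The remaining THBS1 probe sets, which include the brightest one that represented the gene, differed by -0.05 and -0.15 and were higher in 1 of 4 cows. CNN2, an actin-binding calponin, was higher by 0.44 and 0.32 with its 2 probe sets, each in all 4 cows. None of these passed the limma test (adjusted p = 0.993 for each).

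Full minus empty differences did not run in parallel in the 4 cows. Across the 24016 probe sets, which are not independent replicates, they correlated at 0.396 between cows 2 and 4 and at 0.169 between cows 1 and 3. The other pairs gave -0.354 (cows 1 and 4), -0.344 (cows 2 and 3), -0.247 (cows 1 and 2) and -0.022 (cows 3 and 4).

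BOLA-DQB1 had 5 probe sets, and all 5 differed between cows (limma adjusted p from 0.0011 to 0.0256). They did not rank the cows alike. One of them read 5.42 and 5.58 in the libraries of cow 4 and 9.38 to 11.13 in the other cows, while another read 10.30 and 11.01 in cow 4 and 5.58 to 6.39 in cows 2 and 3. For CSN2, the brightest of 3 probe sets did not differ between cows (limma adjusted p = 0.80), but another read 12.07 and 12.43 in cow 2 against 13.47 to 13.82 in the other libraries (limma adjusted p = 0.0348).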
